A study of Mus musculus with 8 samples.

How the data were processed

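Gene expression was measured in dendritic cells sorted by flow cytometry from the bone marrow and from the spleen of 4 mice, on Affymetrix mogene 1.0 ST arrays, a whole-transcript array on which each probe set gathers probes spread along a gene. The bone marrow sample of each mouse was labelled as myeloid dendritic cells and the spleen sample as classical dendritic cells, which gives 2 groups of 4 arrays and 8 arrays in all. The mice were 8 weeks old and carried 1 allele of Cx3cr1 replaced by a gene for green fluorescent protein. Per the labels' protocols, sorted cells went directly into lysis buffer, total RNA was purified with a micro-scale column kit, and biotinylated cDNA was made with a kit for very small inputs from between 100 pg and 2 ng of RNA. Amplification from such inputs can add spread between libraries, and the surface markers used to sort each population are not given in the sources used here.

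The deposited table holds 1 intensity per probe set and array, which the authors made with Affymetrix Expression Console 1.4, per the submitters' processing notes. Background correction, normalization and probe summarization are not given in the sources used here. The deposited intensities were on a linear scale, were all above 0, and had array medians between 125 and 135, which is what arrays already scaled to each other would show. Median intensity was 135, 127, 133 and 125 in bone marrow replicates 1 to 4, and 129, 131, 130 and 135 in spleen replicates 1 to 4. No detection call or background value accompanied the intensities, so whether a dim gene lay above background is unknown, and the fold change of a gene that is dim in 1 group is compressed toward 0 by the background under it. Array intensities have no read depth, and what limits their precision was not tested. The scanner files were not used here.

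Probe sets were paired with genes through a table of the platform's annotation dated 2016. Of 35556 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12146 were not in the gene table. Only probe sets with exactly 1 symbol were named, and of these 21698 had an Entrez gene in a RefSeq table of assembly GRCm38.p6, whose symbol was the same in every case. Of several probe sets for a gene, the one with the highest mean over the 8 arrays was kept, which left 19938 genes, 999 of them with more than 1 probe set. No coordinates are printed, because the source of the probe coordinates was not given in the sources used here.

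Intensities were converted to log2 and the 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), without a filter on dim genes, as bone marrow minus spleen. Log2 fold changes are given with limma's moderated standard error (SE), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are geometric mean intensities of the 4 arrays of a group. A p-value of the main fit sets the difference against the spread among the 4 arrays of each tissue, 1 per mouse, moderated by limma over all genes. That spread holds differences between mice together with those of sorting and amplification. It does not use the pairing of the 2 tissues within a mouse. Arrays with the same replicate number came from the same mouse, per the description labels. Deviations of the 2 arrays of a mouse from their group means had Pearson correlations across genes of 0.096, -0.088, -0.178 and -0.054 for replicates 1 to 4. The labels name no test and no block, so the main fit left the mouse out and a fit with the mouse as a replicate block was run beside it.

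A total of 30 gene lists (cell type markers, antigen presentation, signalling and metabolism) with 579 memberships were fixed before the data were examined. Of these memberships 528 had a value, covering 482 distinct genes; the other members had only a shared probe set or no named one and are not reported here. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the 30 lists, then with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. The named genes also followed a rule fixed before the data were examined. They are the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 4 values in 1 group all lay above the 4 in the other, leaving out predicted genes, small RNAs, receptor gene families of smell and antigen receptor segments. To these were added up to 2 members of each list in each direction with the largest fold past the threshold (or the member with the largest fold where none passed), and a set of dendritic and myeloid identity genes whatever their result. Other list members and genes named below outside this rule were chosen after their values were seen.

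The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, averaging the probe sets of a gene, an intensity trend in eBayes, array weights, the replicate block, testing every probe set, and leaving out each array in turn. Leaving out the 2 spleen arrays with the lowest array weights together was added after the data were examined. Arrays were simulated with the means of these 19938 genes for the bone marrow against spleen comparison. The spread of each gene was drawn at random from the distribution that limma fitted over all genes. The fit recovered 72% of 50 genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 3, with 12 false calls among 198. The simulation changed far fewer genes than the 3681 called in the real data, so 72% is not the sensitivity there. On simulated data camera called all 3 lists shifted by 0.5 and 1 of the 26 lists that shared no gene with them. The simulated genes varied independently, whereas the correlations estimated within the real lists ran from 0.0023 to 0.67. The simulation therefore does not give the rate of false calls among the real lists.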

Results

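Expression was compared between myeloid dendritic cells sorted from bone marrow and classical dendritic cells sorted from spleen, with 4 arrays per group and 1 bone marrow and 1 spleen array from each of 4 mice. Dendritic cells take up antigen and present it to T cells. Those of the spleen are conventionally divided into a cDC1 subset, marked by Xcr1 and Cd8a, and a cDC2 subset, marked by Sirpa and in part by Esam and Cd4. The comparison asks which genes differ between the marrow population and its splenic counterpart. The log2 intensities of arrays of the same group correlated across genes with Pearson's r between 0.993 and 0.996 in bone marrow and between 0.991 and 0.995 in spleen, and arrays of different groups with r between 0.968 and 0.976. Genes are not independent replicates, so these correlations only describe the arrays. The first principal component held 69.1% of the variance and separated the 2 groups, with bone marrow arrays from -31.5 to -26.1 and spleen arrays from 28.1 to 31.9.

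By the naming rule, the 10 genes with the largest rise in bone marrow were C3ar1, Ngp, S100a8, Lcn2, Ltf, Camp, F13a1, Lpl, Cd93 and Mrc1. C3ar1, the receptor of the complement fragment C3a, stood at an intensity of 1858 in bone marrow and 54.9 in spleen (log2 fold change 5.08 ± 0.14 SE, n = 4 per group, limma adjusted p = 2.4e-10). Ngp, which encodes neutrophilic granule protein, stood at 4946 and 146 (5.08 ± 0.11, adjusted p = 2.5e-11). Lpl, the lipoprotein lipase that releases fatty acids from circulating lipoproteins, was higher by 3.86 on the log2 scale, and Mrc1, the macrophage mannose receptor, was 13.7-fold higher. The 10 genes with the largest fall in bone marrow were Apol7c, Dscam, Adam23, Sucnr1, Dnase1l3, Ffar2, Ube2e2, Kit, Gpr4 and Ppp1r14a. Apol7c, an apolipoprotein L family member, stood at 68.2 in bone marrow and 2275 in spleen (-5.06 ± 0.22, adjusted p = 6.9e-09). Sucnr1 and Ffar2, receptors of succinate and of short-chain fatty acids, were 19.4-fold and 14.8-fold lower in bone marrow. Dnase1l3, a secreted nuclease, was 14.9-fold lower, and Kit, the receptor of stem cell factor, was 12.6-fold lower.

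Of 19938 genes, 3681 (18.5%) passed an adjusted p of 0.05 in limma, 1846 of them higher and 1835 lower in bone marrow. Of these, 403 were at least 2-fold higher and 298 at least 2-fold lower. The groups did not overlap in 4100 genes (20.6%), where chance gives 2.86% for 4 arrays against 4, and 3379 of these genes also passed the threshold. The median log2 fold change over all genes was -0.0071.

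**Figure D1:**
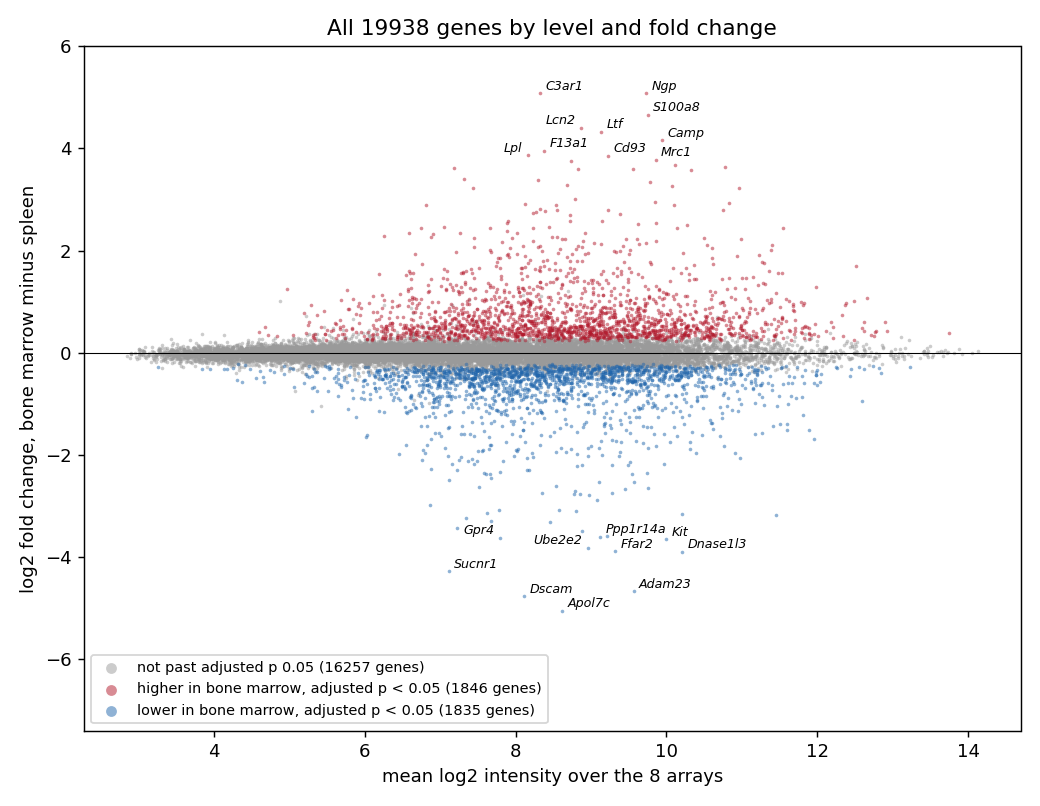
Log2 fold change (bone marrow minus spleen, vertical axis) against mean log2 intensity over the 8 arrays (horizontal axis) for 19938 genes, 1 point per gene, with red for the 1846 genes higher in bone marrow, blue for the 1835 lower and grey for the others. The named points are the 10 genes with the largest rise and the 10 with the largest fall by the naming rule, from C3ar1 at 5.08 to Apol7c at -5.06.

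Genes shared by classical dendritic cells were lower in bone marrow. Of 16 measured genes of this list, 15 were lower, none was higher, and all 16 were lower when adjusted over the list alone (camera adjusted p = 1.0e-19, and adjusted p = 0.044 with an estimated correlation). Zbtb46, a transcription factor of the classical dendritic lineage, was 2.43-fold lower (log2 fold change -1.28 ± 0.11 SE, n = 4 per group, limma adjusted p = 3.3e-06). Flt3, the receptor of the growth factor that dendritic cells depend on, was 2.07-fold lower (-1.05 ± 0.13, adjusted p = 5.6e-05). Spint1, a membrane serine protease inhibitor, had a log2 fold change of -3.59. Itgax, which encodes the integrin CD11c, changed least among the identity genes that passed the threshold in this list, from 8432 in spleen to 6408 in bone marrow (-0.40 ± 0.08, adjusted p = 0.0024). Whether cells were sorted on CD11c or on class II is not given in the sources used here. The genes of the list differed widely in the size of their fall, and markers of macrophages and neutrophils described below were higher in the same bone marrow arrays.

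Within the cDC1 list some markers were much lower in bone marrow while others lay at the level of the spleen. Of 17 measured genes, 10 were lower and 3 higher, the same counts as when adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.12 with an estimated correlation). Xcr1, the receptor of the chemokine Xcl1, was 11.2-fold lower (log2 fold change -3.49 ± 0.24 SE, n = 4 per group, limma adjusted p = 3.4e-07), and Cd8a was 4.07-fold lower (-2.02 ± 0.13, adjusted p = 1.9e-07). Tlr3, a receptor of double-stranded RNA, was 2.62-fold lower. Clec9a, a receptor of dead cells, stood at 1128 in bone marrow and 1043 in spleen (0.11 ± 0.13, adjusted p = 0.69), with a 95% interval of the log2 difference from -0.16 to 0.39. Irf8, a transcription factor of the cDC1 lineage, stood at 2428 and 2523 (-0.06 ± 0.12, adjusted p = 0.86, 95% interval -0.31 to 0.20). The scavenger receptor Cd36 was 3.05-fold higher in bone marrow, and the adhesion molecule Cadm1 was 1.80-fold higher.

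The cDC2 list split in both directions. Of 20 measured genes, 11 were higher and 5 lower in bone marrow, also when adjusted over the list alone (camera adjusted p = 0.018 toward bone marrow, and adjusted p = 0.30 with an estimated correlation). The camera call did not hold with the dimmest 40% of genes left out (adjusted p = 0.057) or without bone marrow replicate 4 (adjusted p = 0.066). The galactose-type lectins Clec10a and Mgl2 were 10.2-fold and 9.31-fold higher (log2 fold changes 3.35 ± 0.12 and 3.22 ± 0.16 SE, n = 4 per group, limma adjusted p = 1.7e-09 and 2.5e-08). Itgam, which encodes CD11b, was 1.81-fold higher. Monocyte and macrophage genes, described below, were higher in the same bone marrow arrays, and whether these members rose within the dendritic cells was not tested. The 5 lower members were Cd7, Dtx1, Clec4a4, Esam and Cd4. Esam stood at 84.9 in bone marrow and 434 in spleen (-2.35 ± 0.13, adjusted p = 3.7e-08), Cd4 was 4.58-fold lower, and Clec4a4 and the Notch target Dtx1 were 6.11-fold and 6.90-fold lower. Cd7 stood at 931 and 8397 (-3.17 ± 0.20, adjusted p = 1.4e-07). Sirpa stood at 6124 in bone marrow and 5430 in spleen (0.17 ± 0.11, adjusted p = 0.40), and Irf4 at 545 and 578 (-0.09 ± 0.16, adjusted p = 0.84).

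**Figure D2:**
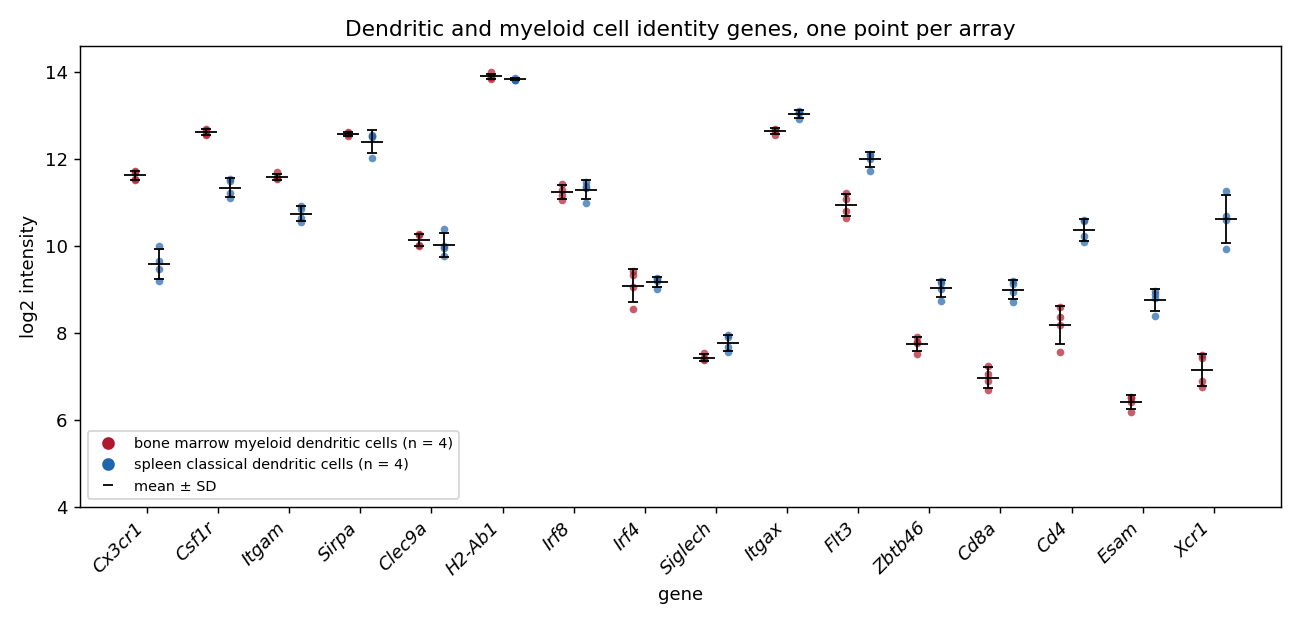
Log2 intensity (vertical axis) of 16 dendritic and myeloid identity genes (horizontal axis, ordered by log2 fold change) in each of 4 bone marrow arrays (red) and 4 spleen arrays (blue), 1 point per array, with the mean and SD in black. Cx3cr1, Csf1r and Itgam lie higher in bone marrow in every array, Clec9a, H2-Ab1 and Irf8 overlap, and Xcr1, Esam, Cd4 and Cd8a lie lower in bone marrow in every array.

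Monocyte and macrophage genes were higher in bone marrow. Of 13 measured classical monocyte genes, 12 were higher and none lower, and 13 were higher when adjusted over the list alone (camera adjusted p = 1.0e-18, and adjusted p = 0.0024 with an estimated correlation). F13a1, the A chain of coagulation factor XIII, stood at 1314 in bone marrow and 84.7 in spleen (log2 fold change 3.96 ± 0.19 SE, n = 4 per group, limma adjusted p = 1.6e-08). Fcgr1, the high-affinity receptor of immunoglobulin G, was 9.69-fold higher and Ccr2, the receptor that monocytes use to leave the marrow, was 6.95-fold higher. Csf1r, the receptor of macrophage colony-stimulating factor, was 2.43-fold higher (1.28 ± 0.10, adjusted p = 1.5e-06). Of 15 non-classical monocyte genes, 11 were higher and none lower, also when adjusted over the list alone (camera adjusted p = 3.4e-08, and adjusted p = 0.14 with an estimated correlation). Cx3cr1, the fractalkine receptor whose locus carries the reporter in these mice, stood at 3162 in bone marrow and 768 in spleen (2.04 ± 0.14, adjusted p = 3.3e-07), and Fabp4 was 5.99-fold higher. Whether either population was sorted on the reporter, which could select for Cx3cr1, is not given in the sources used here.

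Of 20 measured macrophage genes, 16 were higher in bone marrow and none lower, and 17 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.1e-22, and adjusted p = 0.059 with an estimated correlation). Mrc1 (3.77 ± 0.13 SE on the log2 scale, n = 4 per group, limma adjusted p = 1.4e-09) and Axl, a receptor tyrosine kinase that binds dying cells (3.67 ± 0.11, adjusted p = 4.3e-10), were the members with the largest rise. Genes with Fc receptor and complement functions rose with them: 13 of 17 were higher and 1 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 2.8e-15, and adjusted p = 0.041 with an estimated correlation). C1qa, a chain of complement component C1q, stood at 6195 in bone marrow and 500 in spleen (3.63 ± 0.14, adjusted p = 1.9e-09), while Cd55 was the 1 member lower, at 32.6 and 45.3 (-0.47 ± 0.15, adjusted p = 0.0499). The Cd55 call ended without bone marrow replicate 1, 3 or 4 or spleen replicate 2, 3 or 4 (adjusted p from 0.068 to 0.15), with quantile normalization (0.069), median centring (0.077) or array weights (0.083), and without spleen replicates 3 and 4 together (0.42). Of 22 lysosomal genes, 15 were higher and none lower, and 18 were higher adjusted over the list alone (camera adjusted p = 1.2e-13, and adjusted p = 0.058 with an estimated correlation). The protease Ctsd was 3.83-fold higher and Cd63 2.75-fold higher. Among 22 pattern recognition receptors, 11 were higher and 4 lower, or 12 and 4 adjusted over the list alone (camera adjusted p = 4.2e-05, and adjusted p = 0.12 with an estimated correlation), with Tlr8 5.80-fold higher and Clec4a4 and Tlr3 lower. With the mouse as a replicate block, and without bone marrow replicate 2, the complement list had 2 members lower, and without spleen replicate 2 the macrophage list had 1. Of the 20 macrophage genes 8 also stand in another list, so these counts overlap.

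Neutrophil and granule genes showed the largest list median. Of 19 measured genes, 18 were higher in bone marrow and none lower, and all 19 were higher when adjusted over the list alone, with a median log2 fold change of 2.80 (camera adjusted p = 1.3e-33, and adjusted p = 0.018 with an estimated correlation). S100a8, a subunit of calprotectin, stood at 4326 in bone marrow and 171 in spleen (log2 fold change 4.66 ± 0.18 SE, n = 4 per group, limma adjusted p = 1.9e-09). Camp, Ltf and Lcn2, which encode the cathelicidin, lactoferrin and lipocalin of neutrophil granules, were 17.8-fold, 20.1-fold and 21.1-fold higher. Of 10 erythroid genes, 8 were higher and none lower, and 9 were higher adjusted over the list alone (camera adjusted p = 2.9e-08, and adjusted p = 0.12 with an estimated correlation), with the carbonic anhydrase Car1 at 657 in bone marrow and 155 in spleen and Rhag at 48.0 and 20.3. Of 14 basophil, mast cell and eosinophil genes, 8 were higher and none lower, or 10 and 1 adjusted over the list alone (camera adjusted p = 6.8e-05, and adjusted p = 0.13 with an estimated correlation). Among them the eosinophil granule gene Prg2 was 6.71-fold higher and the basophil protease Mcpt8 4.99-fold higher. That count of 8 was 5 without bone marrow replicate 3 or without spleen replicates 3 and 4 together, and also 5 with the dimmest genes left out, which leaves 7 members.

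Of 18 B cell and plasma cell genes, 6 were higher and 7 lower in bone marrow, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.28). The higher members included Vpreb1 (2.31-fold) and Rag1 (1.73-fold), genes of developing B cells, and the lower ones Cd22 (5.10-fold) and Ms4a1 (4.10-fold), genes of mature B cells. Of 17 T cell and NK cell genes, 6 were lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.32 with an estimated correlation). The lower members included Cd5 (-1.81 ± 0.12 SE on the log2 scale, n = 4 per group, limma adjusted p = 1.9e-07) and Klrd1 (2.75-fold lower). Plasmacytoid dendritic cell genes were 4 higher and 4 lower of 16, or 6 and 7 adjusted over the list alone (camera adjusted p = 0.99). Siglech was 1.26-fold lower (-0.34 ± 0.10, adjusted p = 0.028), a call that ended without bone marrow replicate 1, 2 or 3 or spleen replicate 3 or 4 (adjusted p from 0.065 to 0.081), or without spleen replicates 3 and 4 together (0.29). Spib and Ccr9 were 2.53-fold and 2.74-fold lower, and Upb1 and Bst2 were 2.51-fold and 1.72-fold higher. Of 9 megakaryocyte and platelet genes 1 was higher, Pf4, and none lower, also adjusted over the list alone (camera adjusted p = 0.82). Pf4 was 5.43-fold higher with all arrays and 8.93-fold higher without spleen replicate 4. Of 14 stromal and endothelial genes 2 were higher and 1 lower, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.22), with Eng 1.99-fold and Cxcl12 1.46-fold higher and Pecam1 1.53-fold lower. Without bone marrow replicate 2 a T cell and NK cell gene was higher (1 of 17), without bone marrow replicate 3 or with the replicate block a platelet gene was lower (1 of 9), and without bone marrow replicate 4 the stromal list had 2 members lower.

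Of the antigen presentation and maturation lists, only the maturation list passed camera, toward spleen. H2-Ab1, a chain of the class II molecule I-A, stood at 15354 in bone marrow and 14678 in spleen (log2 fold change 0.07 ± 0.07 SE, n = 4 per group, limma adjusted p = 0.69, 95% interval -0.09 to 0.22). Of 13 class II presentation genes, 2 were higher and 4 lower, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.36). By fry, which does not compare a list with other genes, this list moved toward spleen (fry adjusted p = 0.0081). The mean log2 intensity of the list lay between 11.88 and 12.01 in the bone marrow arrays and between 12.17 and 12.28 in the spleen arrays. H2-Ob, a chain of the peptide-loading inhibitor H2-O, was 2.97-fold lower and H2-Eb2 6.30-fold lower, whereas the proteases Lgmn and Ctss were 2.97-fold and 1.39-fold higher. Of 14 class I presentation genes 2 were higher (Canx, Calr) and 2 lower (Psmb9, Psme1), or 3 and 2 adjusted over the list alone (camera adjusted p = 0.88). With the mouse as a replicate block, Calr (adjusted p = 0.071) and Psme1 (adjusted p = 0.10) no longer passed. The Calr call also ended without bone marrow replicate 2 or 4 or spleen replicate 1, 3 or 4 (adjusted p from 0.063 to 0.081), or without spleen replicates 3 and 4 together (0.19). The Psme1 call ended without bone marrow replicate 1, 2 or 3 or any spleen replicate (adjusted p from 0.0505 to 0.13), without spleen replicates 3 and 4 together (0.10), or with median centring (0.11). Of 22 maturation genes, 16 were lower and 1 higher, or 17 and 1 adjusted over the list alone (camera adjusted p = 2.7e-10, and adjusted p = 0.0075 with an estimated correlation). Fscn1, the actin-bundling protein of mature dendritic cells, stood at 168 in bone marrow and 1145 in spleen (-2.77 ± 0.16, adjusted p = 8.8e-08), and Socs2 was 4.37-fold lower. The 1 member higher in bone marrow was the cytokine Il15, by 2.28-fold (1.19 ± 0.10, adjusted p = 1.8e-06). The same bone marrow arrays had higher neutrophil, monocyte and macrophage genes, and whether the maturation genes fell within the dendritic cells was not tested.

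Interferon-stimulated genes were higher and cell cycle genes lower in bone marrow. Neutrophil, monocyte and macrophage genes were higher in the same bone marrow arrays, and whether these shifts lie within the dendritic cells was not tested. Of 22 interferon-stimulated genes, 16 were higher and none lower, also when adjusted over the list alone (camera adjusted p = 1.3e-08, and adjusted p = 0.19 with an estimated correlation). Oas3, an activator of the antiviral nuclease RNase L, was 2.25-fold higher (log2 fold change 1.17 ± 0.17 SE, n = 4 per group, limma adjusted p = 2.1e-04), and Ifi27l2a was 2.02-fold higher. Of 29 cell cycle genes, 22 were lower and none higher, and 26 were lower adjusted over the list alone (camera adjusted p = 2.3e-13, and adjusted p = 0.21 with an estimated correlation). Their median log2 fold change was -0.55. The thymidylate synthase Tyms was 2.22-fold lower (-1.15 ± 0.11, adjusted p = 5.6e-06) and the ribonucleotide reductase subunit Rrm2 was 1.90-fold lower. Of 16 immediate early genes, 5 were higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.32 with an estimated correlation), with Atf3 4.35-fold and Fos 2.09-fold higher and Ier3 1.55-fold lower.

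Chemokine genes were more often higher in bone marrow, and receptors of chemokines divided. Of 24 chemokine genes, 11 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 1.3e-04, and adjusted p = 0.19 with an estimated correlation). Ccl6 stood at 5580 in bone marrow and 1300 in spleen (log2 fold change 2.10 ± 0.11 SE, n = 4 per group, limma adjusted p = 3.0e-08), and Ccl5 was the 1 member lower, by 2.38-fold (-1.25 ± 0.12, adjusted p = 7.0e-06). Of 22 receptors of chemokines and other migration cues, 4 were higher and 8 lower, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.24). Ccr2 and Cxcr2 (5.46-fold) were the members with the largest rise and Xcr1 and Ccr6 (4.05-fold) those with the largest fall. Of 21 inflammatory cytokine and NF-kB feedback genes, 2 were higher (Il27 by 1.37-fold, Nfkbiz by 1.33-fold) and 6 lower, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.29). Ptgs2, the inducible prostaglandin synthase, was 3.02-fold lower and Il12b 1.80-fold lower. The log2 intensity of Ptgs2 varied widely in spleen (9.66, 7.83, 9.49 and 8.02 in replicates 1 to 4). Of 20 factors known from the haematopoietic niche, 5 were higher and 3 lower, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.21), with Igf1 3.75-fold higher and Jag1 2.24-fold and Tnf 1.51-fold lower. The log2 intensity of Igf1 varied widely in bone marrow (8.69, 10.1, 9.14 and 7.42 in replicates 1 to 4), against 6.73 to 7.11 in spleen. With the dimmest genes left out, 3 of the 11 niche factors that remain were higher.

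Of 17 haematopoietic progenitor genes, 7 were higher and 4 lower in bone marrow, also when adjusted over the list alone (camera adjusted p = 0.39). Cd93 was 14.5-fold higher and Cebpa 1.81-fold higher, while Kit and Flt3 were lower. Of 13 glycolysis genes, 6 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.056). Hk3, a hexokinase of myeloid cells, was 2.17-fold higher and the glucose transporter Slc2a3 was 2.73-fold lower (log2 fold change -1.45 ± 0.21 SE, n = 4 per group, limma adjusted p = 2.2e-04). Tpi1 was higher by 0.79 on the log2 scale with all arrays and by 0.49 without spleen replicate 4, and its call ended without bone marrow replicate 2, 3 or 4 (adjusted p from 0.064 to 0.088), without spleen replicates 3 and 4 together (0.072) and with median centring (0.056). The glycolysis list passed without bone marrow replicate 1 (adjusted p = 0.020) or 3 (0.035) or spleen replicate 2 (0.048) or 3 (0.034). The count of 6 higher was 3 without spleen replicates 3 and 4 together, and the count of 1 lower was 2 with quantile normalization. Of 16 cholesterol synthesis genes 1 was lower, the regulator Srebf2 (1.54-fold), and none higher, or 3 lower and 1 higher adjusted over the list alone. The camera adjusted p of this list was 0.071, and it was 0.021 with the mouse as a replicate block, 0.0022 without bone marrow replicate 4 and 0.037 without spleen replicate 2. The count of lower genes was 5 with the block, 3 with the dimmest genes left out, 6 without bone marrow replicate 4 and 2 without spleen replicate 1. With the block, quantile normalization, array weights or the dimmest genes left out, and without spleen replicate 4 alone or with replicate 3, 1 gene of this list was higher.

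**Figure D3:**
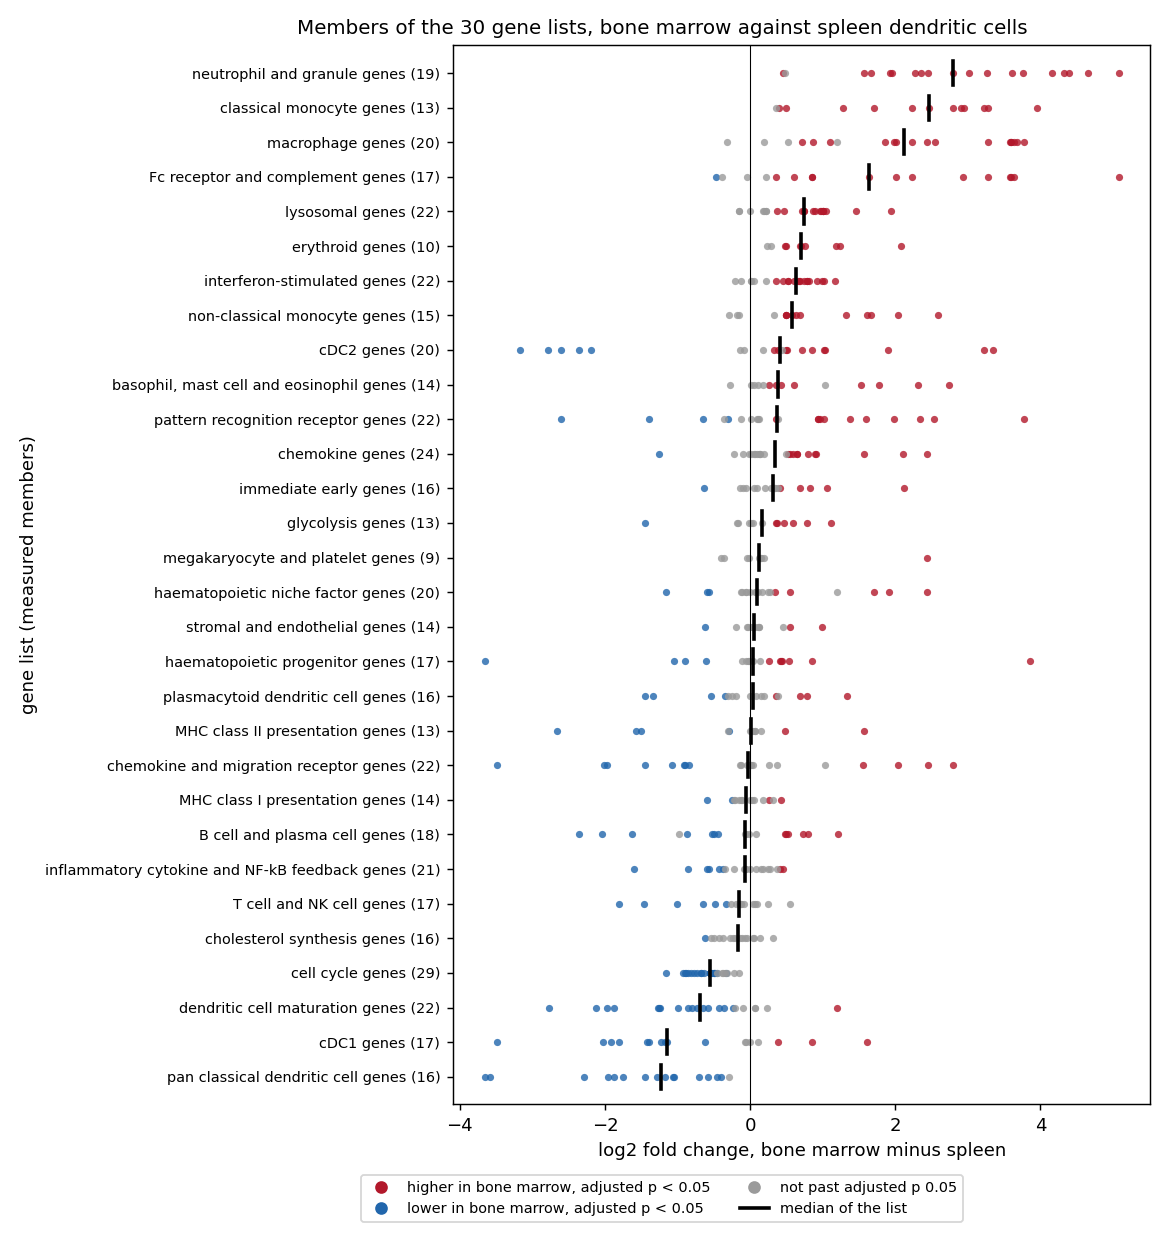
Log2 fold change (bone marrow minus spleen, horizontal axis) of each measured member of the 30 gene lists (vertical axis, ordered by list median, with the number of measured members), 1 point per gene, with red for genes higher and blue for genes lower in bone marrow at an adjusted p under 0.05, grey for the others and a black bar for the list median. The medians run from 2.80 for neutrophil and granule genes to -1.23 for genes shared by classical dendritic cells, and several lists have members far out on both sides.

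Over the 30 lists, camera called 18 at its preset correlation, 13 toward bone marrow and 5 toward spleen, and 5 of these with an estimated correlation. The 5 were the lists of genes shared by classical dendritic cells, classical monocyte genes, neutrophil and granule genes, maturation genes and Fc receptor and complement genes. By fry, which does not compare a list with other genes, 24 lists moved on balance 1 way. The median and the mean of the cDC2 list were 0.41 and 0.053 on the log2 scale. In the lists of plasmacytoid dendritic cell genes (0.037 and -0.029) and of class II presentation genes (0.014 and -0.30), the median and the mean differed in sign, and camera's direction followed the mean.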

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

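The tests of the share of classical dendritic cells, of a single scaling factor per array, of scaling that depends on intensity and of the splits with the mouse as a block were chosen after their results or the data were seen; the others in this part were set before. In 274 sets of 4 values (each named gene, each list mean and the array median, in each tissue) 12 had 1 array far from the other 3 by Dixon's gap test, where chance gives 13.7. In spleen, replicate 4 stood apart for Pf4 (log2 intensity 9.17 against 6.04 to 6.50, gap 0.855 of the range), S100a8 (6.87 against 7.58 to 7.66, gap 0.898), Sirpa (12.02 against 12.52 to 12.56, gap 0.926), Tpi1 (8.77 against 9.88 to 10.1, gap 0.853), the mean of the megakaryocyte and platelet genes (8.35 against 7.26 to 7.40, gap 0.869) and the mean of the cholesterol synthesis genes (8.90 against 8.64 to 8.67, gap 0.87). The mean of the stromal and endothelial genes was lower in spleen replicate 3 (6.64 against 6.76 to 6.78, gap 0.843). In bone marrow, replicate 4 stood apart for Oas3 (9.39 against 8.50 to 8.60, gap 0.893), Ccl5 (9.28 against 8.71 to 8.80, gap 0.844) and Dscam (5.89 against 5.65 to 5.68, gap 0.884), replicate 1 for Fcgr1 (9.92 against 10.4 to 10.5, gap 0.922), and replicate 3 for the mean of the B cell and plasma cell genes (7.214 against 6.988 to 7.005, gap 0.923).

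Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes past the threshold as the tissues did. This was the real one, with 3681 genes, and the highest of the other splits gave 0. Taken over all 35 splits, this treats the 8 arrays as exchangeable, which the pairing by mouse does not allow. The other splits also leave the tissue difference inside their groups, which makes few calls likely. Counted in limma at an unadjusted p of 0.05, the real split gave 5311 genes and the others between 189 and 2085. Only 8 splits part all 4 mice as the real one does, too few for a share under 0.05 (12.5% at the least). Splits that keep the pairing by mouse therefore cannot exclude chance. With the mouse as a replicate block the real split gave 3378 genes and the 7 others 0, or between 71 and 1388 at an unadjusted p of 0.05. The remaining splits put both arrays of some mice on 1 side.

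The granule genes of neutrophils in the bone marrow arrays are a first pattern to follow up. Neither a single scaling factor per array nor scaling that depends on intensity accounts for them, since their median log2 fold change exceeded that of all genes by 2.81 and that of 1000 random lists of like intensity (-0.23 to 0.247) by 2.80; quantile normalization and median centring (lower median 2.80) moved the median of all genes by at most 0.0113 and tested little. Across the 4 bone marrow arrays the 19 members moved together, with a mean pairwise r of 0.573 against a median of -0.0023 over 1000 random lists of like expression, above all of them, which is consistent with one shared source of granulocyte RNA in the bone marrow samples. A granule program that varies within the sorted cells may give the same value, which does not distinguish them. Any sort gate that should have removed granulocytes is not given in the sources used here.

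The macrophage genes moved together in the bone marrow arrays as well (mean pairwise r 0.701, median of random lists 0.0154). One shared source of macrophage RNA predicts this, whether in macrophages among the sorted cells or in the dendritic cells themselves. The comparison with random lists cannot single out such a source here either. If the same foreign RNA carried the granule and the macrophage genes in 1 fixed ratio, their deviations would agree in each bone marrow array. Over 11 macrophage and 13 granule genes at least 4-fold higher in bone marrow, the mean deviations of replicate 2 were 0.462 and -0.306. The difference, granule minus macrophage, was -0.768 with a bootstrap interval over genes, widened for 4 arrays, from -1.21 to -0.473. The intervals of 3 of the 4 bone marrow arrays excluded 0. They treat genes that move together as independent and leave out noise that the genes of a list share within an array. The intervals may therefore be too narrow, and they do not decide against the same foreign RNA. A mixture of separate cell types and a marrow-specific state of dendritic cells both stay open.

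For the classical dendritic cell genes that were lower in bone marrow, neither kind of scaling accounts for the fall, since their median log2 fold change lay at -1.22 relative both to that of all genes and to that of 1000 random lists of like intensity (-0.273 to 0.372). The median after both rescalings (-1.22 at the highest) tested little here too. A lower share of classical dendritic cells among the bone marrow cells would lower each member about equally only if the other cells expressed none of them. Of the members of the pan classical and cDC1 lists, 72.7% (24 of 33) had a 95% interval that missed their common median of -1.17, 13 above and 11 below. These unequal falls argue only against an equal dilution of all members. Cells that express some of the members, and background under dim genes, would also make the falls unequal. A lower share as the whole cause is therefore not excluded. Other cells that express some of the members, and a different mix of dendritic cell subsets, may account for part or all of the fall and were not tested.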

How the results depend on the processing

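The counts of genes past the threshold kept their size (within 1.5 times of 3681) under every alternative run, from 3316 with median centring to 3868 with quantile normalization, 3378 with the replicate block, 3789 over all probe sets, 3144 to 3499 with 1 array left out and 2877 without spleen replicates 3 and 4 together, the last setting chosen after seeing the data. Under quantile normalization 3590 of the 3681 genes were called again, and under the replicate block 3260. With 1 array left out, between 409 (bone marrow replicate 4) and 620 (bone marrow replicate 3) of the 3681 calls were lost. Without spleen replicates 3 and 4 together 977 were lost. No shared gene changed direction under these or the other alternatives that refit the same genes. Shared genes were not counted over all probe sets. The share of called genes that were higher stayed between 48.0% and 53.3%. Camera called 18 to 20 lists with 1 array left out and 5 with an estimated correlation, where the correlation between genes is taken from the residuals of these 8 arrays. Most of the 106 named genes were chosen for passing the threshold with a large fold, so their counts do not stand for all called genes. Of the 106, 101 passed the threshold and 96 of them passed with the same sign in every alternative in which they were tested. The 5 others (Calr, Psme1, Cd55, Siglech and Tpi1) had an adjusted p near the threshold and lost it in at least 1 setting; the cause was not tested. With 1 array left out, Irf4 (higher without bone marrow replicate 3) and Irf8 (higher without bone marrow replicate 1 or spleen replicate 2) turned direction: Irf4 ranged from -0.195 to 0.0928 and Irf8 from -0.161 to 0.0066 on the log2 scale, neither past the threshold in any setting. Camera turned direction, never past the threshold, for plasmacytoid dendritic cell genes with the dimmest genes left out (adjusted p = 0.929), with an intensity trend (0.961), with array weights (0.983) and without spleen replicates 3 and 4 (0.934). It also turned direction with 1 array left out for this list (without bone marrow replicate 1, 2 or 3 or spleen replicate 3), class I presentation genes (without bone marrow replicate 1 or 3 or spleen replicate 3) and megakaryocyte and platelet genes (without bone marrow replicate 3 or spleen replicate 1). Over all 8 arrays left out in turn, turned or not, the adjusted p of these lists ranged from 0.729 to 0.998, from 0.320 to 0.967 and from 0.210 to 0.967. Glycolysis genes ranged from 0.020 to 0.15 and cholesterol synthesis genes from 0.0022 to 0.25 in the same settings. The replicate block changed no call of a named gene or list other than Calr, Psme1 and the cholesterol synthesis list. Array weights were lowest for spleen replicates 3 (0.661) and 4 (0.693) and highest for spleen replicate 2 (1.45). Signal over background was not known, so low intensities limit the fold changes of dim genes.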

Other observations

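The genes in this part were chosen one by one after their values were seen, for their size, and stand for no gene group. The nuclear receptor Pparg was higher in bone marrow by 2.69 ± 0.12 (SE, log2 scale, n = 4 per group), the lipid exporter Abca1 by 2.59, the lipid droplet protein Plin2 by 2.10, Lilr4b by 2.88, Ms4a6d by 2.59 and the transcription factor Maf by 2.08. Gpr82 was lower in bone marrow with a log2 fold change of -3.43, Gpr141b with -3.14, the lymphotoxin gene Ltb with -3.16, the semaphorin Sema7a with -2.30 and the costimulatory receptor Icos with -2.45. Outside the named genes, 649 of the 12146 probe sets that are not in the gene table passed the threshold when all probe sets were tested, 357 higher and 292 lower in bone marrow, and 45 and 64 of the 1621 probe sets with several symbols.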
